A study of Mus musculus with 6 samples.

How the data were processed

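The series measured gene expression by RNA sequencing in 6 libraries of primary hepatic stellate cells from CCl4-treated mice, 3 titled flox and 3 titled Cre, and groups and replicate numbers were taken from the titles. Per the labels' protocols, RNA was extracted with a column kit and 1.3 µg of total RNA entered a SMARTER mRNA library preparation. No cell sort or gate is given. The count table, as deposited, holds raw counts per gene symbol, 1 column per library, with 22966 genes, of which 1349 had 0 counts in every library, and 0 entries without a gene name. A second table holds FPKM values that the authors deposited, and 0 per-sample columns of either table were left unused. The FPKM equal the count divided by the library's total and 1 length per gene. For 11560 genes with over 50 counts in each library, 0 departed from this by over 1e-06 between libraries, so they carry no composition factor. The submitters' processing notes name GRCm38, mm10 and hg38 with no role. The aligner, counter, annotation and use of strand are not given in the sources used here, so named genes with overlapping exons are given with the overlapping gene, and some with close copies as uncertain. Overlaps and positions are from the GENCODE M21 annotation of GRCm38, matched by symbol for 18743 genes.

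Totals of 37273142 to 41006722 counts differ by a factor of 1.10 at most, and 3 counts correspond to 0.0732 to 0.0805 CPM. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14795 and removed 8171. TMM factors were 0.929, 0.905 and 1.01 for flox 1 to 3 and 1.07, 1.06 and 1.04 for Cre 1 to 3. The quasi-likelihood F-test (two-sided) compared the groups with no covariate, and p-values were adjusted by Benjamini-Hochberg, with calls below 0.05. Fold changes are log2 of Cre over flox, and the standard error is the absolute log2 fold change divided by the square root of F. CPM values are TMM-normalised with their SD over 3 libraries, except for the floors of low counts. With 3 libraries against 3, a permutation test cannot go below p = 0.10, so none is given.

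Gene lists, 24 of programmes and 12 of cell type markers with 892 memberships, of which 23 are not analysed here, were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided) where at least 5 members were tested, adjusted over 35 lists. Camera with an estimated correlation and fry were run beside it. Values in brackets after a list's median are its lowest and highest medians over the alternatives planned beforehand in which at least 5 members were tested, each library left out included. They are given where an alternative turned the sign or moved the median by over 1.5 times. Named genes follow a rule with 3 parts: cholinesterase, muscarinic and a few stellate genes always; the 12 genes of largest fold change per direction among those past the threshold, with an average log2 CPM of at least 1 and groups that do not overlap; and the 4 tested members of lowest p in each list, of which a few are not printed. Predicted genes, pseudogenes and immunoglobulin segments are not named. The groups, lists, naming rule, tests and the alternatives below were fixed before the data were examined. These alternatives were RLE size factors, library totals, DESeq2 1.42.0, limma-voom, no count filter, at least 1 CPM in 3 libraries, each library left out, a replicate block, limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1), a mean FPKM of at least 1, and other thresholds. A covariate, the mean log2 CPM of the macrophage list, was added after the results were seen. On the log2(FPKM + 1) scale, fold changes of low genes are understated.

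The methods were tried on simulated counts, drawn for the 14795 genes from the means, library sizes and dispersions of these data. In them 100 genes were changed by 1 and 100 by 2 on the log2 scale, with a planted gene list beside them. For this comparison edgeR called 23% and 74% of the 100 and 100 in the right direction and 5 of 14565 unchanged genes. DESeq2 called 47% and 82% with 83 unchanged genes, limma-voom 23% and 71% with 6, and limma-trend on FPKM 14% and 69% with 4. The genes were drawn independently of each other and without a shift in cell composition. These rates therefore do not carry over to the real libraries, where genes are correlated.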

Results

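RNA sequencing libraries of primary mouse hepatic stellate cells were compared between 3 libraries titled flox and 3 titled Cre. Stellate cells are the retinoid-storing pericytes of the liver, which turn into collagen-producing myofibroblasts after injury. All 6 carried one genotype entry and a carbon tetrachloride (CCl4) treatment entry, a hepatotoxin used to induce liver fibrosis, so the groups rest on the titles alone. The series describes mice lacking butyrylcholinesterase in hepatocytes and asks how the enzyme affects stellate cell activation through muscarinic acetylcholine signalling. The flox libraries held 41006722, 38452088 and 39875268 counts and the Cre libraries 37273142, 39162245 and 39377787. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Spearman correlations across genes, which are not independent replicates, were 0.992, 0.970 and 0.959 between flox libraries and 0.989, 0.984 and 0.977 between Cre libraries, and flox 3 correlated with the Cre libraries at 0.968, 0.964 and 0.975. Every pair differed by more than sampling noise, with a lowest chi-square per gene of 33.4. On the first principal component, with 61% of the variance, flox 3 lay at -6.6, between flox 1 and 2 at -64.3 and -89.3 and the Cre libraries at 39.8 to 63.8.

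Bche, which encodes butyrylcholinesterase (chromosome 3, 73635808 to 73708415 in GRCm38), had few counts: 17, 6 and 21 counts in flox 1, 2 and 3 and 15, 8 and 2 in Cre 1, 2 and 3. Its log2 fold change, Cre over flox, was -0.88 ± 0.80 (standard error, n = 3 per group, edgeR adjusted p = 0.467), less than the spread between replicates. Leaving out 1 library moved it from -1.61 without Cre 1 to -0.41 without Cre 3. The deletion concerns hepatocytes and the libraries stellate cells, so these counts do not check the deletion or the titles. Of the muscarinic receptor genes, Chrm1 had 0 counts in all 6 libraries, which allows up to 0.0732 to 0.0805 CPM, counts scaled by library size, at 3 counts per library. Chrm3 had 1, 1 and 0 counts in flox 1, 2 and 3 and 2, 2 and 8 in Cre 1, 2 and 3, too few for the test. Chrm4 had 13, 26 and 16 counts in flox 1, 2 and 3 and 10, 17 and 3 in Cre 1, 2 and 3, a log2 fold change of -1.004 ± 0.71 (edgeR adjusted p = 0.355). With 1 library left out it ran from -1.57 without Cre 2 to -0.56 without Cre 3. Chrm2 and Chrm5 were not analysed here. Ache, which encodes acetylcholinesterase, had 2, 9 and 1 counts in flox 1, 2 and 3 and 0, 13 and 10 in Cre 1, 2 and 3 and was not tested. Among the 8 tested genes of the cholinergic and muscarinic list, 0 passed the test over all genes and 0 adjusted over the list alone, with a median log2 fold change of -0.27 (from -0.32 without flox 3 to 0.73 without a count filter, camera adjusted p = 0.872). Those of lowest p were Crat, carnitine acetyltransferase, at -0.61 ± 0.19, the choline transporter Slc44a1 at 0.34 ± 0.15, the nicotinic receptor modulator Lynx1 at 0.68 ± 0.31 and the nicotinic subunit Chrnb2 at -0.71 ± 0.36, with edgeR adjusted p of 0.0744 to 0.203. Exons of Crat overlap those of Dolpp1, those of Chrnb2 overlap Adar and those of Slc44a1 an uncharacterised gene. Floors cover counting error only.

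Across 14795 genes tested, Cre libraries had 940 genes higher and 1323 lower than flox libraries at an edgeR adjusted p below 0.05, 15.3% of those tested. Of these, 561 and 866 changed by at least 1 on the log2 scale. The Cre and flox libraries did not overlap for 5861 genes, 39.6%, where chance gives 10% for any single gene. Genes move together, so a chance arrangement of the libraries could separate many of them at once. The genes with the steepest rise were those of the long pentraxin Ptx3 (3.17 ± 0.77), the prostaglandin synthase Ptgs2 (3.17 ± 0.35), the neutrophil-attracting chemokines Cxcl5 (3.02 ± 0.72) and Cxcl3 (2.91 ± 0.72), the hyaluronan-binding protein Cemip (2.76 ± 0.65) and the cysteine-synthesis enzyme Cth (2.73 ± 0.47). Next came the guidance ligand Slit2 (2.69 ± 0.45), Thsd7a (2.64 ± 0.53), the transcription factor Tfcp2l1 (2.60 ± 0.51), the TEAD cofactor Vgll3 (2.55 ± 0.59), the kinetochore scaffold Knl1 (2.50 ± 0.43) and Plscr2 (2.46 ± 0.42). Ptgs2 (chromosome 1, 150100031 to 150108227) stood at 18.8 ± 6.16 CPM in flox and 169.8 ± 60.4 CPM in Cre (SD, n = 3). The steepest falls were those of the B cell-attracting chemokine Cxcl13 (-6.29 ± 0.66), Chp2 (-5.89 ± 1.32), the haemoglobin scavenger receptor Cd163 (-5.78 ± 0.97), Paqr9 (-5.32 ± 0.74), Tmem273 (-5.23 ± 0.998) and the Cdc42 exchange factor Fgd2 (-5.16 ± 0.59). They were followed by the inflammasome sensor Nlrp1b (-5.12 ± 0.85), the ADP receptor P2ry12 (-5.07 ± 1.10), the potassium channel Kcna2 (-5.00 ± 0.99), the eosinophil-attracting chemokine Ccl24 (-4.99 ± 0.66), the B cell scaffold Bank1 (-4.87 ± 0.70) and the transporter Abcg3 (-4.65 ± 0.66). Cxcl13 (chromosome 5, 95956951 to 95961068) stood at 23.4 ± 15.4 CPM in flox and 0.296 ± 0.134 CPM in Cre, and Cd163 (chromosome 6, 124304656 to 124330527) at 62.5 ± 57.9 CPM in flox and 1.14 ± 0.726 CPM in Cre. The edgeR adjusted p values of these 24 genes ran from 0.0226 to 0.0431. None of them was assigned to a cell type, since the libraries also hold macrophage RNA. Reads of P2ry12 cannot be told apart from those of Med12l, whose exons overlap it, and those of Nlrp1b, Plscr2 and Abcg3 from close family members, since the counting is not given in the sources used here. Leaving out flox 1, flox 2, Cre 1 or Cre 2 left 0 genes past the threshold in edgeR, with 3720, 3562, 3593 and 3978 at an unadjusted p below 0.05. Leaving out flox 3 gave 5329 and leaving out Cre 3 gave 1369. No other tool was run with a library left out. All 6 libraries gave 4334 genes in DESeq2 and 1404 in limma-voom. Scaling to library totals, which shifts the median of all genes by 0.16, turned the split to 1415 higher and 1066 lower, or 57.0% higher against 41.5%, and limma-trend on a mean FPKM of at least 1 gave 59.6%.

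**Figure D1:**
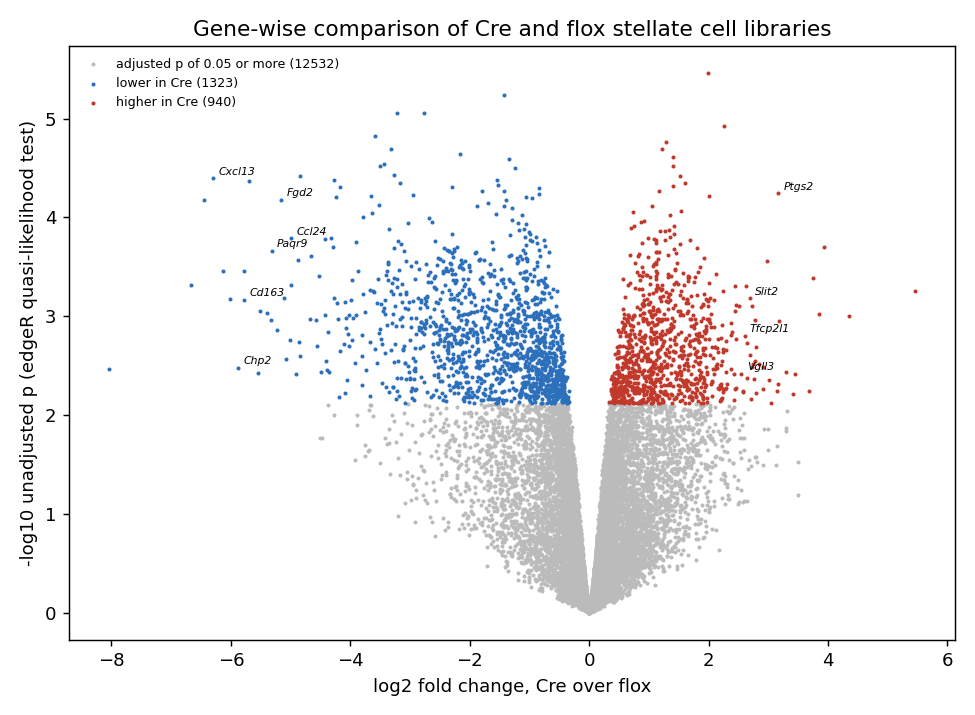
The log2 fold change of each tested gene, Cre over flox, on the x axis against -log10 of its unadjusted edgeR p on the y axis, for 3 flox and 3 Cre libraries. Red points are the 940 genes higher and blue points the 1323 genes lower in Cre at an adjusted p below 0.05, and the steepest labelled fall is that of Cxcl13 at -6.29.

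The markers of macrophages and Kupffer cells, the resident macrophages of the liver, were far lower in the Cre libraries. In this list 16 of 24 members fell and 0 rose, 21 and 0 when adjusted over the list alone, with a median log2 fold change of -2.81 (camera adjusted p = 6.31e-15, and adjusted p = 0.588 with an estimated correlation). The scavenger receptor Marco fell from 2308 ± 391 to 239 ± 99.1 CPM, a log2 fold change of -3.27 ± 0.34. The secreted macrophage protein Cd5l (-3.65 ± 0.41), the phosphatidylserine receptor Timd4 (-4.32 ± 0.57) and the efferocytosis kinase Mertk (-1.84 ± 0.26) fell too. The mean of the list was 8.35, 8.78 and 6.92 log2 CPM in flox 1, 2 and 3 and 5.69, 5.38 and 5.84 in Cre 1, 2 and 3, so flox 3 stood nearest to the Cre libraries. Its flox average, 8.02, exceeded those of the stellate activation (5.74), collagen (6.13) and quiescent stellate lists (3.67) described below. In Cre it was 5.63, against 6.15, 6.51 and 3.63. The lists hold different genes, so these levels are not shares of cells. Dendritic cell markers were lower too, with 3 of 11 falling and 0 rising, the same counts when adjusted over the list alone, and a median of -0.77 (from -1.27 without Cre 3 to -0.11 on log2(FPKM + 1), camera adjusted p = 0.0435, and adjusted p = 0.588 with an estimated correlation). They were the transcription factors Irf8 (-1.33 ± 0.19) and Batf3 (-2.02 ± 0.50) and the lectin receptor Clec9a (-1.75 ± 0.43), whose exons overlap those of Clec1b, while the activation marker Cd83 was at -1.16 ± 0.40 (edgeR adjusted p = 0.0959). Macrophages also carry Irf8, so a fall of dendritic cells cannot be told apart here from the macrophage fall.

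Mesothelial markers were higher as a list. The median was 1.40 (from 0.82 without Cre 2 to 1.82 without Cre 3), with all 13 members on the positive side although 0 of 13 passed alone, also when adjusted over the list alone (camera adjusted p = 0.0200, and adjusted p = 0.707 with an estimated correlation). The transcription factors Bnc1 and Wt1 were at 1.79 ± 0.50 and 1.42 ± 0.45, the surface protein Gpm6a at 2.03 ± 0.65 and Lrrn4 at 1.52 ± 0.54, with edgeR adjusted p of 0.0567 to 0.0995. The list mean was 5.22 and 5.52 log2 CPM in Cre 1 and Cre 2 but 3.56 in Cre 3, against 3.80 ± 0.26 (SD) in flox. Hepatocyte markers had a median of -0.99 (from -1.11 without flox 1 to -0.34 without flox 3) with 0 of 27 past the test over all genes or over the list alone (camera adjusted p = 0.0640). Albumin (Alb) was at 272 ± 179.9 CPM in flox and 120.5 ± 81.0 CPM in Cre, a log2 fold change of -1.17 ± 0.70 (edgeR adjusted p = 0.275). With 1 library left out it ran from -1.69 without Cre 3 to -0.50 without flox 3. The protease inhibitors Serpina1e and Serpina1a, paralogs whose reads are hard to separate, were at -1.10 ± 0.36 and -1.64 ± 0.55, transthyretin (Ttr) at -1.71 ± 0.62 and the cytochrome Cyp3a11 at -2.76 ± 1.06, none of them past the test. In the endothelial list 3 of 23 members fell, 4 when adjusted over the list alone, and 0 rose. The median was -0.06 (from -0.36 without Cre 2 to 0.25 without flox 3) and becomes 0.07 with library totals (camera adjusted p = 0.192). The mannose receptor Mrc1 (-1.66 ± 0.27), which macrophages also carry, the water channel Aqp1 (-2.16 ± 0.48) and the lectin Clec4g (-2.22 ± 0.53), overlapping a predicted gene, fell, while Vwf was at -1.75 ± 0.47 (edgeR adjusted p = 0.0517).

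The other cell type lists did not pass. B and plasma cell markers had 2 of 10 members lower, 3 over the list alone, and 1 higher. The median was -0.15 (from -0.66 without flox 3 to 0.05 without flox 1) and becomes 0.02 with library totals (camera adjusted p = 0.200). The lectin receptor Cd22 (-3.90 ± 0.52) and Bank1 fell and the transcription factor Pax5 (1.58 ± 0.28) rose, with Cd79b at -3.34 ± 1.09. T and NK cell markers had 0 of 21 past the test on either adjustment. The median was -0.28 (from -0.68 without Cre 3 to -0.02 without Cre 2, camera adjusted p = 0.200). Cd4 was at -2.58 ± 0.76, Cd3d at -1.56 ± 0.63, Il7r at -1.26 ± 0.60 and Cd2 at -0.97 ± 0.53. Of 9 neutrophil markers 1 fell, the cytokine receptor Csf3r (-1.86 ± 0.43), the same count when adjusted over the list alone, and the median was 0.30 (from 0.08 on log2(FPKM + 1) to 0.70 without a count filter, camera adjusted p = 0.686). Trem1 was at 1.74 ± 0.63, Lcn2 at 1.34 ± 0.69 and Il1r2 at 1.001 ± 0.57. Cholangiocyte markers had 1 of 12 members higher, the RNA-binding protein Bicc1 (1.46 ± 0.35), and 1 lower, Prom1 (-2.51 ± 0.65), the same counts over the list alone. Their median was 0.13 (from -0.20 without Cre 1 to 0.34 without Cre 3) and their mean -0.11 (camera adjusted p = 0.872, upward). Osteopontin (Spp1) was at -2.24 ± 0.96 and Epcam at -0.77 ± 0.46. In the portal fibroblast list 2 of 15 members rose, Slit2 and the matrix glycoprotein Fbln2 (1.16 ± 0.25), the same count over the list alone. Cd34, overlapping a predicted gene, was at 1.79 ± 0.53 and Fbln1 at 1.24 ± 0.41. Its median was -0.27 (from -0.28 in DESeq2 to 0.62 at 1 CPM or more), its mean 0.13 and the camera direction upward (adjusted p = 0.254). Vascular smooth muscle markers had 0 of 13 past the test on either adjustment. The median was 0.23 (from 0.06 without flox 3 to 0.77 without flox 1, camera adjusted p = 0.385). Smtn, overlapping a predicted gene, was at 0.78 ± 0.21, Synpo2 at 1.03 ± 0.34 and Cspg4 at -1.40 ± 0.55. The erythroid and platelet list had 4 tested members, below the minimum for a list test, with Ppbp at -1.53 ± 0.58, Car2 at 0.61 ± 0.31, Pf4 at -0.60 ± 0.52 and Itga2b at -0.03 ± 0.32, none past the test on either adjustment.

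With 1 library left out, the macrophage call held each time. The dendritic call ended, at camera adjusted p of 0.275 without flox 3 and 0.0548 without Cre 1, and the mesothelial call ended at 0.131 without flox 3, 0.0548 without Cre 1 and 0.0796 without Cre 2. Over the alternatives planned beforehand, the dendritic list was past the threshold in 11 of 18 and the mesothelial list in 12 of 18. The hepatocyte list was past the threshold in 10 of 18 alternatives planned beforehand, among them 0.00340 without flox 1, 0.0416 without flox 2, 0.0205 without Cre 1 and 0.0109 without Cre 3. Other lists that came past the threshold with 1 library left out were the endothelial list at 0.0323 without flox 2 and 0.00118 without Cre 2, the T and NK cell list at 0.0276 without Cre 3 and the B and plasma cell list at 0.0242 without flox 3, which was past the threshold in 3 of 17 alternatives planned beforehand.

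**Figure D2:**
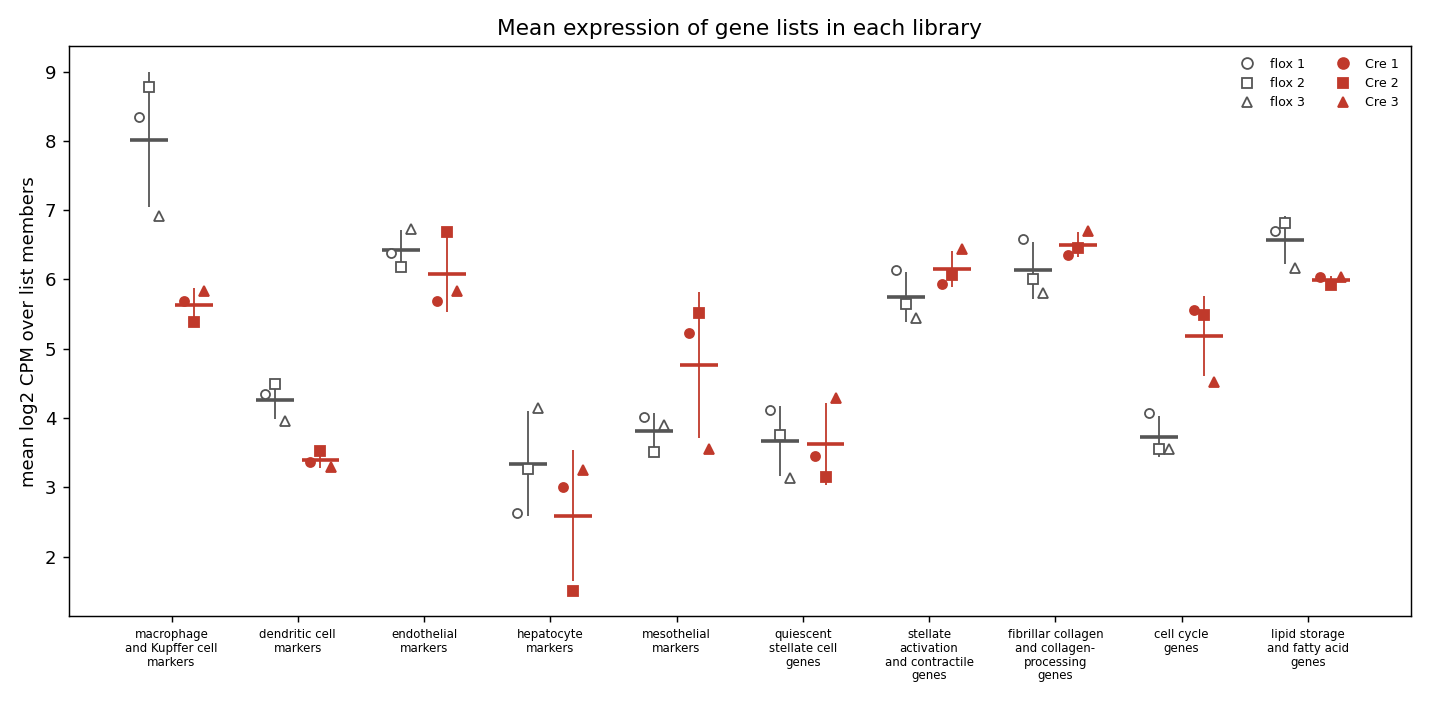
Mean log2 CPM over the tested members of 10 gene lists (y axis) in each library, with open grey symbols for flox 1 to 3, filled red symbols for Cre 1 to 3, horizontal bars for group means and vertical lines for 1 SD either way (n = 3). The macrophage list averages 8.02 ± 0.97 in flox and 5.63 ± 0.24 in Cre, and the cell cycle list 3.73 ± 0.30 and 5.19 ± 0.58.

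The stellate activation and contractile list was higher in the Cre libraries, and its members moved unevenly. In it, 8 of its 28 tested members rose and 1 fell, and 11 and 2 did when adjusted over the list alone. The median log2 fold change was 0.58 (from 0.49 without Cre 3 to 0.97 without flox 1, camera adjusted p = 0.00227, and adjusted p = 0.588 with an estimated correlation). The collagen cross-linking enzyme Lox (1.47 ± 0.21), the metalloproteinase inhibitor Timp1 (1.20 ± 0.20), the matrix glycoprotein Thbs1 (1.13 ± 0.21) and N-cadherin, Cdh2 (1.33 ± 0.25), rose. Timp1 (chromosome X, 20870166 to 20874735) stood at 66.9 ± 18.7 CPM in flox and 154 ± 12.4 CPM in Cre (SD, n = 3). Tgfb1, the gene of the profibrotic cytokine TGF-beta 1, fell, from 255 ± 46.2 to 138 ± 35.1 CPM (-0.88 ± 0.22, edgeR adjusted p = 0.0431, and 0.0507 in limma-voom). Over the alternatives planned beforehand its adjusted p ran from 0.00336 in DESeq2 to 0.162 without Cre 1, and with the macrophage list mean as a covariate, chosen after the data were seen, its log2 fold change was -0.08 (edgeR adjusted p = 0.941). Acta2, which encodes the smooth muscle actin that marks myofibroblasts (chromosome 19, 34241090 to 34255590), stood at 55.4 ± 23.4 CPM in flox and 109.8 ± 20.3 CPM in Cre, with each Cre library above each flox library. Its log2 fold change of 0.99 ± 0.30 did not pass (edgeR adjusted p = 0.0696), but did in DESeq2 (adjusted p = 0.0146), with library totals (0.0427) and on FPKM of at least 1 (limma-trend, 0.0362). Over the alternatives planned beforehand its adjusted p ran from 0.0146 to 0.179, the highest without flox 2. The PDGF receptor gene Pdgfrb was at 0.54 ± 0.47 and desmin (Des) at -0.70 ± 0.43, with edgeR adjusted p of 0.452 and 0.296. With 1 library left out, Pdgfrb ran from -0.10 without Cre 3 to 0.88 without flox 1 and Des from -1.09 without Cre 3 to -0.41 without flox 1. The list means of flox 1, 2 and 3 were 6.14, 5.64 and 5.44 log2 CPM and those of Cre 1, 2 and 3 5.94, 6.06 and 6.44, so the groups overlapped. The macrophage markers moved the other way between the groups and fell by a median of 2.81 on the log2 scale. Among the flox libraries, flox 3 was lowest in both lists, with a macrophage list mean of 6.92 log2 CPM. Mesothelial markers were higher, at a median of 1.40, but not in Cre 3, which had the highest activation mean. Their mean there was 3.56 log2 CPM, against 4.01, 3.51 and 3.9 in flox 1, 2 and 3.

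The fibrillar collagen genes Col1a1, Col1a2 and Col3a1 did not pass, while some other collagen and collagen-processing genes did. In the collagen list, 7 of its 30 tested members rose and 2 fell, and 9 and 2 did when adjusted over the list alone. The median was 0.44 (from 0.33 without flox 3 to 0.79 without flox 1, camera adjusted p = 0.00531, and adjusted p = 0.707 with an estimated correlation). Col1a1 was at 471 ± 290.1 CPM in flox and 623 ± 186 CPM in Cre, a log2 fold change of 0.41 ± 0.45 (edgeR adjusted p = 0.550), Col1a2 at 0.35 ± 0.50 and Col3a1 at -0.17 ± 0.61. With 1 library left out, these ran from 0.10 without flox 3 to 1.03 without flox 1 for Col1a1, from -0.01 without Cre 2 to 1.03 without flox 1 for Col1a2 and from -0.59 without Cre 3 to 0.61 without flox 1 for Col3a1. The collagen chaperone Serpinh1 (1.17 ± 0.21), the short-chain collagen Col8a1 (2.02 ± 0.37) and the lysyl hydroxylase Plod2 (1.42 ± 0.28) rose, and the lysyl hydroxylase Plod1 (-1.18 ± 0.25) fell. The collagen list means were 6.59, 6.01 and 5.8 log2 CPM in flox 1, 2 and 3 and 6.35, 6.46 and 6.7 in Cre 1, 2 and 3, so the groups overlapped. Without flox 3, the camera adjusted p rose to 0.0641 for the activation list and 0.164 for the collagen list. Of TGF-beta target genes, 7 of 26 rose and 2 fell, 8 and 2 over the list alone. The median was 0.24 (from 0.04 without Cre 3 to 0.40 on log2(FPKM + 0.1), with 0.37 without flox 1, camera adjusted p = 0.0441, and adjusted p = 0.588 with an estimated correlation). The inhibitory Smad7 (1.20 ± 0.19) and Ldlrad4 (1.05 ± 0.19), the latter overlapping Fam210a, rose with the latent TGF-beta binding protein Ltbp2 (1.22 ± 0.25), which overlaps an uncharacterised gene. This call was past the threshold in 7 of 18 alternatives planned beforehand, with p of 0.0103 to 0.588, and ended at 0.250 without flox 3 and 0.222 without Cre 3. Among metalloproteinases and their inhibitors 4 of 20 rose, Timp1, the stromelysins Mmp3 (2.003 ± 0.36) and Mmp10 (1.70 ± 0.31) and Adam12 (1.40 ± 0.26), and 0 fell, 5 and 1 over the list alone. The median was 0.26 (from 0.18 without Cre 3 to 0.50 without flox 1) and the camera adjusted p 0.0728, and the list was past the threshold in 4 of 18 alternatives planned beforehand, among them 0.0189 without flox 1, 0.0416 without flox 2 and 0.0393 without Cre 2. The macrophage markers fell by a median of 2.81 on the log2 scale between the same groups. The mesothelial list was higher, at a median of 1.40, but not in Cre 3, which had the highest collagen mean. The mesothelial mean there was 3.56 log2 CPM, against 4.01, 3.51 and 3.9 in flox 1, 2 and 3.

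**Figure D3:**
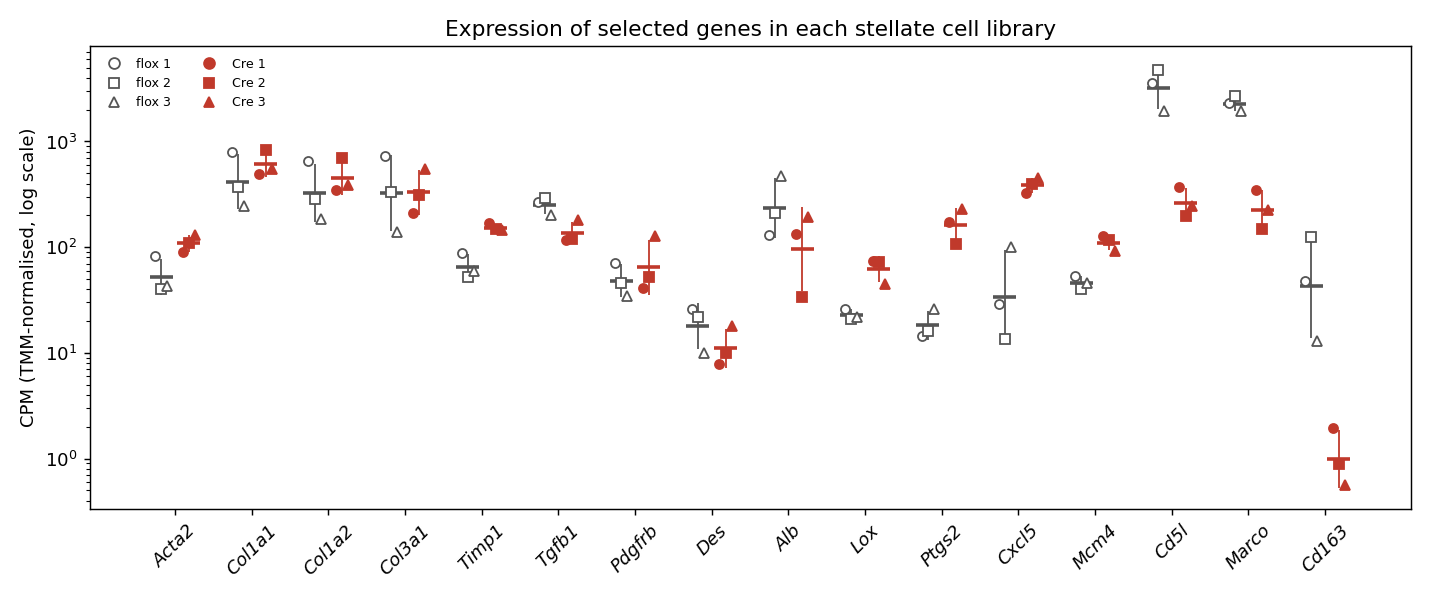
TMM-normalised CPM on a log axis for 16 genes in each library, with open grey symbols for flox 1 to 3, filled red symbols for Cre 1 to 3, horizontal bars for geometric means and vertical lines for 1 SD either way on the log2 scale (n = 3). Acta2, Timp1, Lox, Ptgs2, Cxcl5 and Mcm4 lie above every flox library in all 3 Cre libraries, and Cd5l, Marco, Cd163 and Tgfb1 below, whereas Col1a1, Col1a2, Col3a1, Pdgfrb, Des and Alb overlap.

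Genes of the quiescent, lipid-storing state went both ways. In the quiescent stellate list 2 of 27 members rose and 3 fell, 3 and 3 over the list alone, with a median of 0.16 (from -0.37 without Cre 3 to 0.52 without Cre 2), a mean of 0.01 and a camera adjusted p of 0.928. The lectin Fcna (-2.67 ± 0.33), whose exons overlap its antisense neighbour Fcnaos, the lipid droplet protein Plin2 (-1.14 ± 0.20) and the nuclear receptor Pparg (-2.29 ± 0.43) fell, and the proteoglycan decorin, Dcn (1.22 ± 0.28), rose. Lrat, the enzyme that esterifies retinol for storage, was low at 1.68 ± 1.35 CPM in flox and 0.651 ± 0.439 CPM in Cre and did not pass (-1.36 ± 1.07, edgeR adjusted p = 0.399). Its fold change ran from -1.91 without flox 3 to -0.87 without Cre 2 with 1 library left out. Retinoid metabolism genes had 4 of 19 lower and 0 higher, 6 and 2 over the list alone. The median was -0.37 (from -0.51 without Cre 3 to -0.00242 at a mean FPKM of at least 1, camera adjusted p = 0.130). Lipoprotein lipase, Lpl (-2.01 ± 0.32), the retinoid receptor Rxra (-1.08 ± 0.20), the retinal reductase Dhrs3 (-0.64 ± 0.13) and the retinoic acid hydroxylase Cyp26b1 (-1.53 ± 0.35) fell. The lipid storage and fatty acid list was lower, with 6 of 20 members falling and 3 rising, 10 and 3 over the list alone. The median was -0.50 (from -0.81 without a count filter to -0.09 on log2(FPKM + 1), camera adjusted p = 0.0323, and adjusted p = 0.707 with an estimated correlation). The camera adjusted p was 0.0796 without Cre 2. Plin2 and Lpl fell here with the adipogenic factor Cebpa (-2.60 ± 0.45) and the triglyceride lipase Pnpla2 (-0.82 ± 0.15). Macrophage markers fell by a median of 2.81 on the log2 scale between the same libraries.

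Cell cycle genes rose together. Of 35 tested members 32 rose and 0 fell, 33 and 0 over the list alone. The median was 1.67 (camera adjusted p = 1.37e-17, and adjusted p = 0.588 with an estimated correlation). The replication helicase genes Mcm4 (1.27 ± 0.17) and Mcm5 (1.32 ± 0.22), cyclin A2, Ccna2 (1.98 ± 0.33), and the mitotic transcription factor Foxm1 (1.88 ± 0.33) had the lowest p, and the last 2 overlap exons of Exosc9 and Tex52. Mcm4 stood at 46.4 ± 6.70 CPM in flox and 112 ± 18.3 CPM in Cre (SD, n = 3). Hypoxia and glycolysis genes were higher as a list, with 4 of 25 rising and 0 falling on either adjustment and a median of 0.45 (camera adjusted p = 0.00210, and adjusted p = 0.588 with an estimated correlation). They were the angiogenic factor Vegfa (0.97 ± 0.15), the glucose transporter Slc2a1 (0.90 ± 0.22) and the glycolytic enzymes Pfkl (0.84 ± 0.22) and Eno1 (0.59 ± 0.16). In the Wnt and Hedgehog list, which holds pathway members besides targets, 5 of 20 rose and 0 fell on either adjustment. The median was 0.70 (from 0.27 on log2(FPKM + 1) to 0.998 without flox 1, camera adjusted p = 0.00215, and adjusted p = 0.588 with an estimated correlation). The camera adjusted p was 0.0581 without flox 3. The Hedgehog effector Gli3 (1.52 ± 0.21), overlapping a predicted gene, the receptors Fzd1 (0.89 ± 0.14) and Smo (1.03 ± 0.22) and the ligand Wnt5a (1.68 ± 0.35) were among them. Cytosolic ribosomal protein genes had 4 of 41 higher and 0 lower, and 0 over the list alone. The median was 0.20 (from 0.18 without flox 3 to 0.36 on log2(FPKM + 0.1), camera adjusted p = 0.00227, and adjusted p = 0.707 with an estimated correlation). Rplp0 (0.43 ± 0.11), Rps2 (0.45 ± 0.11) and Rpl12 (0.46 ± 0.12) were among those that rose, the last 2 overlapping Snhg9 and Lrsam1, with processed pseudogenes whose reads cannot be told apart here. Cholesterol synthesis genes had 0 of 22 past the test on either adjustment and a median of 0.30 (from 0.21 without Cre 2 to 0.45 with library totals, camera adjusted p = 0.0435, and adjusted p = 0.707 with an estimated correlation). Sc5d was at 0.95 ± 0.25 and Fdft1, overlapping Ctsb, at 0.78 ± 0.24. That call was past the threshold in 8 of 18 alternatives planned beforehand, with p of 0.0107 to 0.707, and ended at 0.0522 without flox 1, 0.104 without flox 3 and 0.282 without Cre 2. The cholesterol list means overlapped, at 4.19 log2 CPM in Cre 3 and 4.22 in flox 3. In the p53 and senescence list 1 of 22 members rose and 4 fell, 4 and 5 over the list alone, with a median of 0.08 (from -0.05 without flox 1 to 0.27 on log2(FPKM + 0.1)) and a mean of 0.01 but a downward camera direction (adjusted p = 0.928). The apoptosis gene Pmaip1 (-1.88 ± 0.22) and the stress genes Gadd45a (-1.08 ± 0.14), overlapping an uncharacterised gene, and Sesn1 (-2.11 ± 0.44) fell and Igfbp3 (1.64 ± 0.27) rose. The mesothelial list was higher, at a median of 1.40, and macrophage markers fell by a median of 2.81 on the log2 scale beside all of these groups. In Cre 3 the mesothelial mean, 3.56 log2 CPM, was not above flox. The cell cycle mean was also lowest of the Cre libraries in Cre 3, at 4.52.

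Inflammatory cytokine and chemokine genes were higher as a list in the same libraries. Of 34 members 5 rose and 2 fell, the same counts over the list alone. The median was 0.83 (from 0.30 without Cre 3 to 1.09 without flox 3, camera adjusted p = 0.0109, and adjusted p = 0.707 with an estimated correlation). The camera adjusted p was 0.371 without Cre 3. The list means were 6.23, 5.97 and 6.85 log2 CPM in flox 1, 2 and 3 and 6.89, 6.49 and 7.73 in Cre 1, 2 and 3, so the groups overlapped. Ptgs2, Cxcl5 and the acute-phase protein Saa3 (1.37 ± 0.25) rose and Cxcl13 fell. Antigen presentation genes were lower, with 4 of 19 members falling, 5 over the list alone, 0 rising and a median of -0.40 (from -0.55 without flox 3 to -0.15 without Cre 2, with -0.25 without flox 2, camera adjusted p = 0.0200, and adjusted p = 0.707 with an estimated correlation). The camera adjusted p was 0.118 without Cre 2. They were the immunoproteasome genes Psmb9 (-0.91 ± 0.19), overlapping Tap1, and Psmb8 (-0.51 ± 0.12), the class II chaperone H2-DMa (-2.27 ± 0.50), overlapping Brd2, and the class Ib gene H2-T23 (-0.52 ± 0.12). The antigen presentation list means overlapped too, at 7.23 log2 CPM in Cre 3 and 7.05 in flox 3. Interferon response genes had 8 of 32 lower and 0 higher on either adjustment. The median was -0.05 (from -0.14 without flox 2 to 0.14 on log2(FPKM + 0.1)) and becomes 0.10 with library totals. The camera adjusted p was 0.0798, and the list was past the threshold in 3 of 18 alternatives planned beforehand, among them 0.0485 without flox 1 and 0.00984 without flox 2. Ifi27l2a (-1.51 ± 0.28), the RNA sensor regulator Dhx58 (-0.74 ± 0.14) and the oligoadenylate synthetases Oas3 (-1.49 ± 0.29) and Oas2 (-1.03 ± 0.21) fell. Immediate-early and dissociation stress genes had 3 of 30 lower and 1 higher on either adjustment. The median was -0.32 (from -0.34 without Cre 1 to -0.16 on log2(FPKM + 1), camera adjusted p = 0.0728, and past the threshold in 4 of 18 alternatives, among them 0.0329 without flox 1, 0.0416 without flox 2 and 0.0158 without Cre 3). The AP-1 subunits Jun (-0.76 ± 0.10), overlapping Junos, and Fos (-1.49 ± 0.34) fell with Klf2 (-0.86 ± 0.22), and the chaperone Hsp90aa1 (0.76 ± 0.19) rose. Saa3, Oas2, Oas3, H2-T23 and Hsp90aa1 have close copies whose reads cannot be told apart here. These groups sit beside macrophage markers that fell by a median of 2.81 on the log2 scale.

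The remaining signalling and metabolic lists did not pass. PDGF receptor signalling genes had 1 of 20 higher and 3 lower, 2 and 3 over the list alone, with a median of 0.19 (from 0.11 without Cre 3 to 0.35 on log2(FPKM + 0.1)) and a mean of -0.01 (camera adjusted p = 0.629). The receptor Pdgfra (1.20 ± 0.27) rose, and the adaptor Grb2 (-1.31 ± 0.24), the leukocyte kinase subunit Pik3cd (-2.39 ± 0.44) and the ligand Pdgfc (-1.87 ± 0.45) fell. Gq and calcium signalling genes, the route by which some muscarinic receptors act, had 5 of 30 lower and 1 higher, 9 and 3 over the list alone. Their median was -0.10 (from -0.26 with the replicate block to 0.06 with library totals, camera adjusted p = 0.160). The kinase genes Prkcb (-1.69 ± 0.28) and Camk2b (-2.25 ± 0.43), the phospholipase Plcb2 (-3.49 ± 0.69) and the G protein regulator Rgs2 (-3.32 ± 0.69) fell. Integrin and focal adhesion genes had 4 of 24 higher and 1 lower, 7 and 4 over the list alone. The median was 0.30 (from 0.18 without Cre 3 to 0.45 on log2(FPKM + 0.1), camera adjusted p = 0.142). Vinculin, Vcl (0.85 ± 0.13), overlapping Ap3m1, caveolin, Cav1 (1.48 ± 0.34), and Itga3 (1.34 ± 0.32) rose and paxillin, Pxn (-0.47 ± 0.10), fell. Oxidative phosphorylation genes had 0 of 34 past the test on either adjustment. The median was -0.16 (from -0.28 without flox 3 to 0.01 on log2(FPKM + 0.1)) and becomes 0.00 with library totals (camera adjusted p = 0.0640, and past the threshold in 3 of 18 alternatives, among them 0.0297 without flox 3 and 0.0447 without Cre 1). Those of lowest p were Cox5a at -0.78 ± 0.22, Sdhc at -0.51 ± 0.16, Ndufb8 at -0.52 ± 0.17 and Sdhb at -0.59 ± 0.20. Of oxidative stress genes 5 of 24 fell and 0 rose on either adjustment. The median was -0.16 (from -0.31 without Cre 3 to 0.01 on log2(FPKM + 0.1), camera adjusted p = 0.0795, and past the threshold in 3 of 18 alternatives, 0.0281 without flox 1, 0.0369 without flox 2 and 0.0286 without Cre 3). They included the peroxiredoxin Prdx1 (-0.70 ± 0.13), the ferritin light chain Ftl1 (-1.07 ± 0.24), which has pseudogenes, and the glutathione peroxidases Gpx1 (-1.80 ± 0.43) and Gpx3 (-2.19 ± 0.55). Unfolded protein response genes had 1 of 25 higher, asparagine synthetase, Asns (1.32 ± 0.20), and 1 lower, Ddit3 (-0.53 ± 0.10), on either adjustment, with Chac1 at 1.02 ± 0.35 and Xbp1 at -0.44 ± 0.19. The median was 0.07 (from 0.01 without flox 3 to 0.23 on log2(FPKM + 0.1), camera adjusted p = 0.629). Macrophage markers fell by a median of 2.81 on the log2 scale between the same groups. Of all 35 tested lists camera called 14, 0 with an estimated correlation, where the lowest adjusted p was 0.588, and 0 in fry, where it was 0.0848. Fry's mixed test, which asks whether members change in either direction, passed for 30.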

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

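The macrophage score covariate was chosen after seeing the data, and all other alternatives were planned and all were run. All 2263 calls kept their direction in every alternative planned beforehand that tested the gene, and 83.7% with the covariate. The groups did not overlap for any of the 940 higher and 1323 lower genes. Another tool or a left-out library could thus hardly turn a direction, and the kept directions add no support of their own. Counts of changed, higher and lower genes were 2244, 904 and 1340 with RLE size factors, 2134, 896 and 1238 without a count filter, 2321, 984 and 1337 at 1 CPM or more. They were 2322, 1383 and 939 on a mean FPKM of at least 1, with 59.6% higher. They were 2481, 1415 and 1066 with library totals. They were 4334, 1976 and 2358 in DESeq2, where 4 adjusted p were NA, 1404, 578 and 826 in limma-voom. They were 931, 453 and 478 on log2(FPKM + 0.1), 3986, 1826 and 2160 at an adjusted p below 0.10 and 1427, 561 and 866 with a log2 fold change of at least 1 either way. They were 0, 0 and 0 in limma-trend on log2(FPKM + 1) (5778 at an unadjusted p below 0.05) and 0, 0 and 0 in edgeR with the macrophage score covariate (1776). With each library left out they ran from 0 to 5329 changed, 0 to 2447 higher and 0 to 2882 lower, 0 without flox 1, flox 2, Cre 1 or Cre 2, 5329 without flox 3 and 1369 (771 and 598) without Cre 3. The cause was not tested. Fewer samples lower the power, which does not account for the rise to 5329 without flox 3. On the first principal component flox 3 lay apart, at -6.6, from flox 1 and 2, at -64.3 and -89.3. Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.033, -0.105 and -0.056, and each Cre library correlated best with a flox library of another number. With the replicate block, edgeR called 0, 0 and 0 genes (4296 at an unadjusted p below 0.05, lowest adjusted p 0.0736), 10 programme lists and 4 cell type lists; no other tool was run with the block. Called programme lists ran from 8 to 12 in alternatives with all libraries and camera at its preset, and from 7 (without flox 3) to 15 with 1 library left out. Cell type lists ran from 2 to 5, with 5 without flox 2, without Cre 3 and on log2(FPKM + 0.1). Both were 0 in camera with an estimated correlation and 0 in fry. The activation list had adjusted p = 0.588 with an estimated correlation, 0.101 in fry, and 9.06e-06 to 0.0641 with each library left out; the collagen list had 0.707, 0.172, and 8.35e-07 to 0.164, the upper ends without flox 3. Of 170 named genes tested, the 117 called, for which this was nearly fixed as above, and 49 of the 53 uncalled kept their direction in all alternatives planned beforehand. The activation and collagen lists stayed higher with the macrophage score covariate (camera adjusted p = 0.000144 and 0.000201). Acta2 and Col1a1 were then at log2 fold changes of 1.44 and 1.62 and did not pass (edgeR adjusted p = 0.491 and 0.609). With the macrophage score covariate, the direction turned for the inflammatory (camera adjusted p = 0.673), antigen presentation (0.807), oxidative phosphorylation (0.000201), cholesterol (0.842), lipid storage (0.470) and T and NK cell (0.000735) lists, and for 14 called genes, whose log2 fold changes became Tmem273 0.27, Kcna2 0.31, Plod1 0.10, Pparg 0.00540, Cyp26b1 0.18, Plcb2 0.47, Fos 0.29, Oas2 0.0208, H2-DMa 0.52, Ftl1 0.0396, Gpx1 0.69, Gpx3 0.98, Sesn1 0.12 and Batf3 0.27. The cause was not tested, and the covariate itself does not overlap between the groups. The B and plasma cell and the cholinergic lists gave no value at a mean FPKM of at least 1. Depth limits Bche and the muscarinic receptors, at 26 counts or fewer per library.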

Other observations

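The lists of serine and one-carbon genes and of scar-associated macrophage genes, and the tests of total-count scaling, of the macrophage share on other lists, of stellate cell number and of mesothelial cells, were chosen after the results they concern were seen; the tests with pan-macrophage genes, gene length and tRNA synthetases were set before their values were seen, as were the splits. Genes of serine synthesis, one-carbon metabolism and amino acid uptake were higher in the Cre libraries, and all 17 of 17 rose in edgeR, at a median log2 fold change of 1.29. The mitochondrial folate enzyme Aldh1l2 (1.999 ± 0.14), the serine synthesis enzymes Phgdh (1.52 ± 0.16) and Psat1 (1.40 ± 0.14), Mthfd1l (1.40 ± 0.15) and the mitochondrial carboxykinase Pck2 (1.29 ± 0.12) had edgeR adjusted p of 0.0226 each. Phgdh stood at 54.9, 47.7 and 40.5 CPM in flox 1 to 3 and 156, 119 and 136 in Cre 1 to 3. The list mean was 4.63, 4.43 and 4.77 log2 CPM in flox 1 to 3 and 6.09, 5.75 and 5.98 in Cre 1 to 3. Since its members were seen before, the list's camera p of 5.25e-21 (p = 0.0271 with an estimated correlation) is no independent evidence. 1 of the 17 genes, Asns, is also in the unfolded protein response list. A candidate explanation is a shared amino acid response programme. It was tested on genes of cytosolic aminoacyl-tRNA synthetases and of the tRNA exporter Xpot, of which 8 of 12 rose and 12 were positive, at a median of 0.578 (camera p = 1.33e-06, and p = 0.174 with an estimated correlation). Without Xpot, 7 of 11 synthetases rose, at a median of 0.579. The median lay above the level set beforehand. The unfolded protein response list, which shares Asns, had a median of 0.07. In it 1 of 25 members, Asns, rose and 1, Ddit3 (-0.53 ± 0.10), fell. The shared programme remains a hypothesis, since cell composition differs between the same libraries. Cell cycle genes were higher too, at a median of 1.67, and the synthetase test does not separate the 2 patterns.

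Genes known from scar-associated macrophages of fibrotic liver split flox 3 from the other flox libraries. Trem2 stood at 136, 178 and 8.93 CPM in flox 1 to 3 and 9.26, 13.7 and 10.4 in Cre 1 to 3, Gpnmb at 4985, 5016 and 496 CPM in flox 1 to 3 and 576, 515 and 1105 in Cre 1 to 3 and Spp1 at 1441, 1855 and 75.2 CPM in flox 1 to 3 and 219, 207 and 288 in Cre 1 to 3. The median over the 6 genes was -2.03, and 1 of 6, Lgals3, fell in edgeR (-1.60 ± 0.42, adjusted p = 0.0473). 4 of the 6 are also in another list.

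Macrophage markers were lower in Cre, at a list median of -2.81, and -2.63 with library totals. Library totals shift the median of all genes by only 0.16, so the choice between these scalings is too small to account for the fall. The size of that shift fixed the outcome beforehand, so it adds no support of its own. Fewer macrophages in the Cre preparations may account for the lower markers: 20 pan-macrophage genes outside that list, 0 of them in any other fixed list, had a median of -2.06, with 17 lower and 0 positive (camera p = 2.26e-15, and p = 0.118 with an estimated correlation). Of the abundant members, picked after their values were seen, Laptm5 (-2.60 ± 0.50) and Itgb2 (-2.10 ± 0.33) fell, with Laptm5 at 947, 1229.8 and 309 CPM in flox 1 to 3 and 126, 111 and 174 in Cre 1 to 3, but Cybb (-1.50 ± 0.40) and Arhgdib (-0.59 ± 0.24) did not pass (edgeR adjusted p = 0.0513 and 0.133). Some of the 20 genes, such as Ptprc and Cd53, are carried by other leukocytes too, so they do not single out macrophages. How many of these genes stellate cells express was not tested. The fall was uneven, at medians of -2.81 for the macrophage list and -2.06 for these genes. A difference in macrophage number in the livers of the mice behind the Cre and flox titles and a difference in cell isolation stay open and untested, as the labels give neither.

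Stellate activation genes were higher in Cre. A smaller macrophage share would raise every other cell type's genes alike, and relative to the endothelial list the activation list differed by 0.764 ± 0.484 (standard error, log2) with overlapping groups, against 0.790 ± 0.312 without overlap relative to the mean of the endothelial, hepatocyte and quiescent stellate lists. These references differ, so a smaller macrophage share and a change within stellate cells cannot be told apart. Among the flox libraries, flox 3 had the lowest macrophage and the lowest activation list mean (6.92 and 5.44 log2 CPM). A smaller macrophage share alone would put its activation mean higher, but this rests on flox 3 alone. More stellate cells in the Cre preparations also stay open, since the quiescent stellate list mean differed by -0.0397 ± 0.448, and its members go both ways. The activation list shares 12 of its 30 genes with other lists.

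Cell cycle genes were higher in Cre. The difference was 1.82 ± 0.454 relative to the endothelial list and 1.84 ± 0.568 relative to the mean of 3 lists, without overlap in either. This argues against an even rise of all other cell types' genes, from a smaller macrophage share, as the whole cause. The endothelial and hepatocyte lists themselves had mean log2 fold changes of -0.37 and -0.76. The endothelial list also holds Mrc1, which macrophages carry. A shift in the shares of the other cell types thus stays open. A gene length trend is too small to account for the rise. The deciles of shortest and longest genes had median log2 fold changes of -0.14 and 0.16, against 1.67 for the list. Removing a smooth trend on length gave 1.77, an outcome largely fixed by the size of that trend. More mesothelial cells in the Cre preparations stay open: with the mesothelial list mean as a covariate the difference was 0.931 ± 0.215, but 1.003 ± 0.967 without Cre 3; the most abundant mesothelial genes were Lrrn4, at 63.8 CPM in flox and 184 in Cre, and Krt8, at 70.5 and 70.5, and 2 of the 13 markers are in another list. A difference in proliferation of stellate cells was not tested.

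The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2263 genes, 940 higher and 1323 lower, against 0 at most in any other split, so 1 of 10 was as large for each. For programme lists 3 of 10 splits gave as many as the real 11, with 13 at most in another split, and for cell type lists 8 of 10 gave as many as 3, with 5 at most. The activation list's adjusted p of 0.00227 was matched or passed in 3 of 10 splits, down to 1.69e-14, and the collagen list's 0.00531 in 4 of 10, down to 2.14e-18. Both lowest values came from flox 1, Cre 2 and Cre 3 against the others.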
